A study of Mus musculus with 435 samples.

How the data were processed

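The series holds 435 spotted 2-colour arrays of mouse liver, each from a mouse of strain A/J or strain C57 on a high-fat or a low-fat diet. The labels place them in 44 groups by strain, diet and week, with week 0, week 1 and weeks 3 to 11 present. Per the labels, liver total RNA carried Cy5 on every array, and a pooled reference RNA from 10 tissues of C57 mice, liver included, carried Cy3. The labels say neither which arrays share a mouse nor when each array was hybridised.

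The deposited values are ratios on a linear scale, in which the mean ratio of every array over its measured probes is 1. That scaling, the positive direction (liver over reference) and the linear scale were read from the values, since the labels state no image analysis, background subtraction, spot filter or normalization. Among the measured values 0.251% are below 0 and 0.271% are equal to 0, and 42.4% of all cells are empty. A log2 of each positive ratio was taken from the deposited ratios with no pseudocount, and values at or below 0 were treated as not measured. Signal intensities and background levels are not in the files, so the signal behind each ratio is unknown and only the number of arrays limits the precision given here.

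Of the 17280 probe positions, 14717 have an entry in the gene table that came with the series, 14711 of them with 1 symbol and 6 with several. For 14416 probes the Entrez identifier matched the mouse gene table of assembly GRCm38.p6, used only to update symbols. No genome build is stated for the array and no coordinates are given. The number of measured probes per array ran from 194 to 14929, with a median of 10791. It was lower at week 0, where the median was 5007, than at the later weeks, where it was 11235. Identical columns were found for 2 pairs of A/J high-fat arrays, and each pair was counted once, which left 433 arrays.

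Each array was centred on its median log2 ratio over the probes tested. Probes were tested if measured on at least 70% of arrays and on at least 3 arrays of every group. The comparisons over weeks 1 to 11 used 1 mean log2 ratio per group, so that the week is the unit of replication, because arrays of a group could share an error that their own spread does not show. Limma 3.58.1 in R 4.3.3 was fitted to these means with 4 strain-by-diet levels and a term for each week. The contrasts were high-fat minus low-fat in C57 and in A/J, the difference between those, and C57 minus A/J on the low-fat diet. Adjusted p-values are Benjamini-Hochberg values over all probes tested in a contrast, with a threshold of 0.05. Straight lines against week were fitted with limma to the weekly diet differences and to the low-fat means. Diet was also compared at each week with limma on single arrays, as was week 0, for which the labels give a diet too. These weekly p-values measure the spread between arrays of a group, which may be partly technical.

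Lists of genes for liver metabolism, stress and immune responses, other cell types and housekeeping complexes, 30 in all, were fixed before the data were examined. They were tested with camera from limma at a preset correlation of 0.01 where at least 5 members were measured, and again with an estimated correlation and with fry. Each gene was represented by the probe measured on most arrays. The rule for naming genes, also fixed before the data were examined, takes the 6 largest rises and the 6 largest falls past the threshold with the same sign in at least 9 of 10 weeks, and the 3 members with the smallest p of any list with at least 3 members past it. Members of the hepatocyte list and genes known to differ between these strains were reported whatever their p.

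A second fit was added after the data had been seen. It leaves out week 8 and 4 other arrays that correlate with the median of all arrays below 0.15, and holds 350 arrays in 36 groups over 9 weeks. Because the probe filter asks for 3 arrays in every group, the fit over all weeks tests 2711 probes and the fit over 9 weeks tests 7195. Genes are named from both fits, and in the second the same sign was asked in at least 8 of 9 weeks.

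The code was tested on simulated values drawn with the spread of the real groups. In the diet comparison of C57 over all weeks, 75% of probes given a log2 change of 0.5 and 100% of those given a change of 1 were called, with 8 of 2511 unchanged probes called. Over 9 weeks the corresponding figures were 88%, 100%, and 13 of 6995. In the diet comparison of A/J at week 4, 71% of probes given a log2 change of 1 and 97% of those given a change of 2 were called. Each change was given to 100 probes, against 2 and 17 probes called in the real C57 comparisons. More changed probes make the adjusted threshold easier to pass, so these shares may overstate what could be found there. Errors were drawn independently between probes, and at week 4 no error shared by the arrays of a group was simulated.

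Alternatives fixed before the data were examined were no centring, quantile normalization, a looser filter (30% of arrays, 2 per group) and a stricter filter (95% of arrays), leaving out arrays that stand apart from their group, group medians, single arrays as replicates with and without a block for the sample number, each strain fitted on its own, leaving out each week, averaging consecutive arrays and pooling the spread of all 44 groups in the weekly tests. Other groupings of the arrays, 100 per result with a fixed seed, were drawn by exchanging labels within weeks for the comparisons over weeks and the lists, by permuting the weeks for the straight lines, and by regrouping the arrays of both diets at random for the weekly tests.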

Results

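Liver expression was measured on 435 arrays from A/J mice (218 arrays) and C57 mice (217 arrays) to follow how a high-fat and a low-fat diet act over time. A/J and C57 are inbred laboratory strains. Each strain and diet was followed at 11 times, week 0, week 1 and weeks 3 to 11. Of the 44 groups of strain, diet and week, 40 have 10 arrays, 3 have 9 and 1 has 8. Values are log2 ratios of liver over a pooled reference of 10 tissues, centred per array. The week is the unit in the comparisons over weeks, in which SE is the standard error from limma and SD the spread of the weekly group means.

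Genes typical of hepatocytes lay above the pooled reference, and genes of its other tissues lay mostly below it. All 20 measured hepatocyte genes were above 0, with a median log2 ratio of 0.74, among them the apolipoprotein genes Apoa1 (1.76) and Apoe (1.41), the thyroxine carrier Ttr (1.39), transferrin Trf (1.23) and albumin Alb (1.14). Of 20 genes of the other reference tissues 13 were below 0, with a median of -0.35. The lowest were the muscle actin Acta1 (-2.73), the kidney gene Umod (-2.70) and the brown fat gene Ucp1 (-2.40).

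Most arrays of week 8 lacked this pattern. At week 8, 9 of 10 A/J high-fat arrays, 10 of 10 A/J low-fat arrays and 9 of 10 C57 high-fat arrays correlated with the median of all arrays at only 0.0457 to 0.0957, and none of the 10 C57 low-fat arrays did. In these 28 arrays the hepatocyte genes had a median of -0.14 and the other tissues' genes one of -0.13. A further 4 arrays correlated below 0.15, namely 1 each of A/J high-fat week 5 (0.149) and A/J low-fat week 10 (-0.0298), and 2 of C57 low-fat week 6 (0.0477 and 0.125). The remaining arrays ran from 0.245 to 0.788. Gene values below come from the 9 weeks without week 8 and without those 4 arrays unless stated, a choice made after the data had been seen, and counts are given for both fits. The weekly tests use all arrays unless stated.

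**Figure D1:**
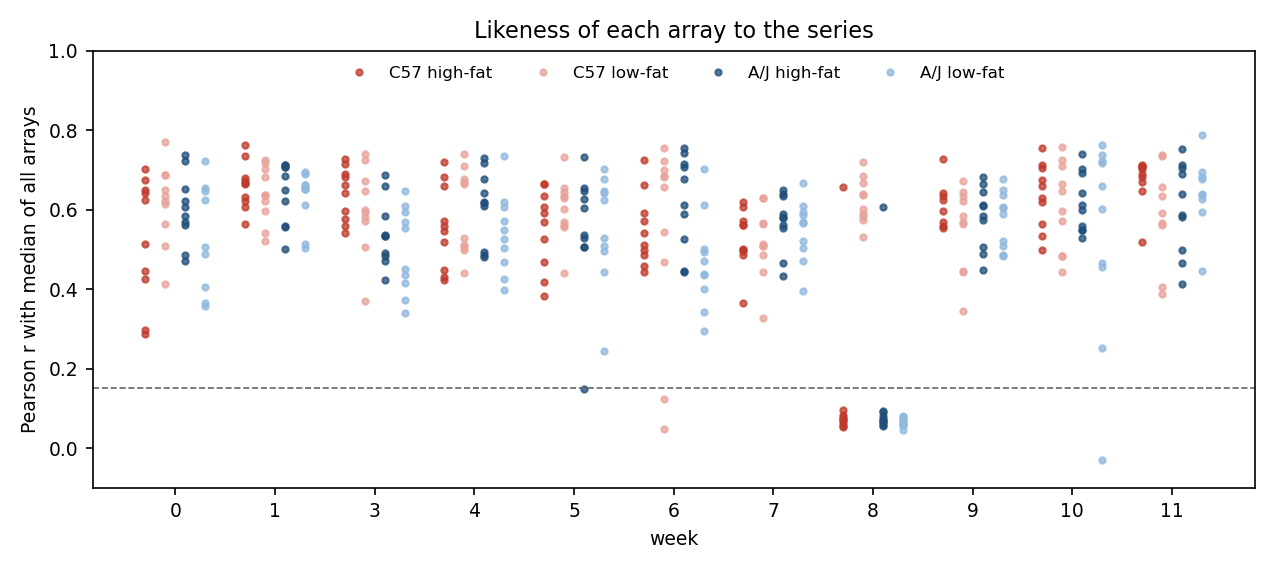
Pearson correlation of the log2 ratios of each array with the median of all arrays (vertical axis), by week (horizontal axis), with 1 point per array coloured by strain and diet. The dashed line marks 0.15, and 28 arrays of week 8 and 4 others lie below it.

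In C57 Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, was higher on the high-fat diet by a log2 difference of 1.11 ± 0.19 (SE, 9 weeks), or 2.16-fold. Its mean log2 ratio was 1.40 ± 0.74 (SD) on the high-fat and 0.29 ± 0.38 on the low-fat diet. The kinesin motor gene Kif21a was higher by 0.84 ± 0.11, the endoplasmic reticulum isomerase gene Fkbp11 by 0.63 ± 0.12, the secreted Wnt-pathway ligand gene Ndp by 0.55 ± 0.10, the translation initiation factor gene Eif3f by 0.53 ± 0.10 and Tmem238l by 0.48 ± 0.09. Secisbp2, whose protein is needed to make selenoproteins, was lower (-0.85 ± 0.13), as were the mitochondrial nucleoside diphosphate kinase gene Nme4 (-0.70 ± 0.13), the crystallin gene Crybb1 (-0.56 ± 0.13) and the glutathione S-transferase gene Gstm3 (-0.42 ± 0.09). Scd1, Kif21a, Ndp, Eif3f, Tmem238l, Secisbp2, Nme4 and Crybb1 kept their sign in 9 of 9 weeks, and Fkbp11 and Gstm3 in 8. A second Fkbp11 probe had a log2 difference of -0.24. Gstm3 was lower in the high-fat groups at week 0 too, at -1.15 ± 0.28 in C57 (limma adjusted p = 0.823, n = 6 and 4) and -0.56 ± 0.22 in A/J (adjusted p = 0.432, n = 8 and 3).

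In limma with Benjamini-Hochberg adjustment the adjusted p was 6.94e-05 for Kif21a, 0.00214 for Secisbp2, 0.00476 for Scd1, 0.00774 for Ndp, Eif3f and Nme4, 0.00962 for Fkbp11 and Tmem238l, and 0.0488 for Crybb1 and Gstm3. In all, 17 of 7195 probes passed the threshold, 12 higher and 5 lower on the high-fat diet, and 14 of them have a symbol. The others with a symbol, Kcnd2 (0.43), Cda (0.36), Csgalnact2 (0.32) and Ppp2r2d (0.30), fall outside the rule for naming genes and were named after their values were seen. Over all 10 weeks limma called 2 of 2711 probes, both also among the 17. These were Kif21a (0.85 ± 0.11, adjusted p = 3.04e-05, 10 of 10 weeks) and Gstm3 (-0.46 ± 0.09, adjusted p = 0.0247, 9 of 10 weeks), while Scd1 was not testable there because too few week 8 arrays measured it. This fit includes week 8, in which 9 of 10 C57 high-fat arrays were unlike the rest. In the same fit Eif3f (0.54, limma adjusted p = 0.0611), Nme4 (-0.61, adjusted p = 0.0758), Fkbp11 (0.34, adjusted p = 0.818) and Tmem238l (0.18, adjusted p = 0.90) did not pass. Fkbp11 (0.45, adjusted p = 0.0701) and Tmem238l (0.26, adjusted p = 0.378) did not pass over 9 weeks with quantile normalization either. Leaving out 1 week in turn kept Scd1, Kif21a, Secisbp2 and Nme4 past the threshold in 9 of 9 fits, and Crybb1 and Gstm3 in 3. The count was 9 without week 1, 6 without week 5 and 9 without week 9.

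**Figure D2:**
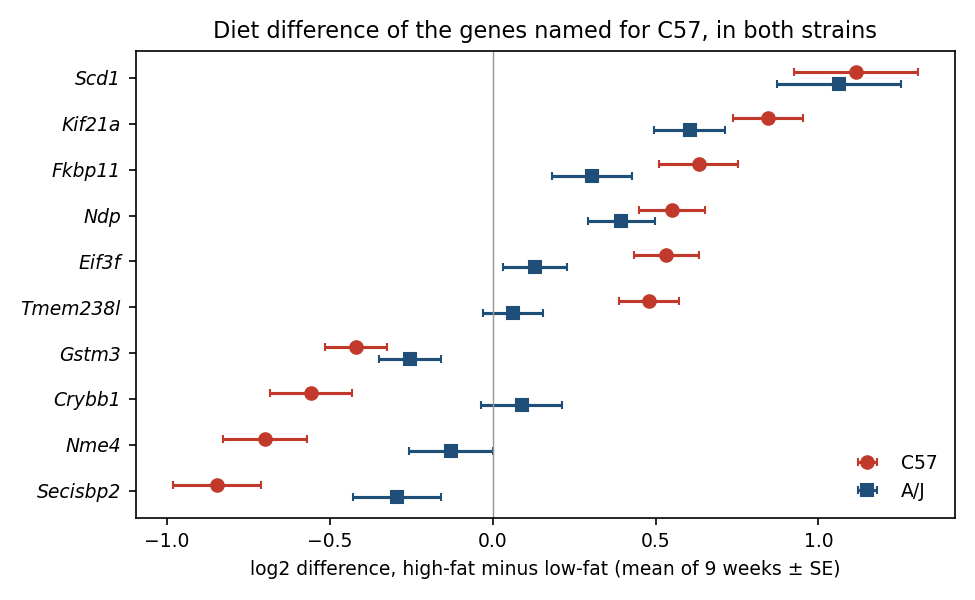
Log2 difference between high-fat and low-fat diet (horizontal axis, mean over 9 weeks, bars are the SE from limma) of the 10 genes named for C57, in C57 (circles) and A/J (squares). Scd1 lay at 1.11 in C57 and 1.06 in A/J, and Crybb1 at -0.56 and 0.09.

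Genes of fatty acid oxidation and ketogenesis were higher as a group in C57 on the high-fat diet, with 14 of 19 measured members positive, a median log2 difference of 0.09 and an adjusted p of 0.0311 in limma's camera. The call was lost with an estimated correlation (adjusted p = 0.183 with an estimated correlation), and none of its members passed on its own, over all probes or adjusted over the list alone. Its largest values were those of Cyp4a14 (0.41), Ehhadh (0.37) and Bdh1 (0.25), which act in fatty acid hydroxylation, peroxisomal oxidation and ketone body metabolism. Genes of cytosolic ribosomal proteins were lower as a group, with 30 of 39 negative, a median of -0.07 and a camera adjusted p of 0.0311, again without a single member past the threshold over all probes or adjusted over the list alone. Rpl13a had the largest fall in value (-0.36), and the call was lost too (adjusted p = 0.566 with an estimated correlation). With each week left out in turn both calls held in 5 of 9 fits, and 6 of 100 groupings of the weekly means gave as many lists, so chance cannot be excluded.

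Among 15 genes of fatty acid and triglyceride synthesis only Scd1 passed the threshold, over all probes and adjusted over the list alone, and the list's camera adjusted p was 0.15. Elovl5 (0.47) and Agpat2 (0.31) had positive values that did not pass, and the synthase gene Fasn was near 0 (0.04). Of the 24 genes of xenobiotic metabolism only Gstm3 passed, and none of the 5 lipid droplet genes did (Cd36 0.02, Cidec 0.02). Of the hepatocyte genes 0 of 16 passed over all probes, while 3 were higher adjusted over the list alone, Apoe (0.39), Apoc3 (0.33) and Apoa2 (0.25), as was Igf2 (0.28) among 4 genes of young liver. Markers of skeletal muscle were negative in 7 of 7 cases (median -0.11, camera adjusted p = 0.270), markers of stellate cells and matrix in 8 of 10 (median -0.07, adjusted p = 0.285), and those of macrophages and leukocytes were positive in 8 of 11 (median 0.05, adjusted p = 0.285). Only 2 genes of cholesterol synthesis and no red blood cell marker were measured widely enough to be tested. Over all 10 weeks only 10 lists had enough measured members, and camera in limma called 0 of them in any of the 4 comparisons, with 0 at an unadjusted p under 0.05 in each.

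In A/J Scd1 was higher on the high-fat diet by 1.06 ± 0.19, or 2.09-fold, and Kif21a by 0.60 ± 0.11. The difference of Scd1 was 1.14 at week 0 already, against 0.74, 0.67 and 0.58 at weeks 1, 3 and 4. Mean log2 ratios of Scd1 were 0.77 ± 0.59 (SD over 9 weeks) on the high-fat and -0.30 ± 0.47 on the low-fat diet, and those of Kif21a were 0.56 ± 0.35 and -0.05 ± 0.22. Both were higher on the high-fat diet in 9 of 9 weeks (limma, adjusted p = 0.0154 for each), and they were the only calls among 7195 probes with centring. The count was 3 without centring, 5 after quantile normalization (4 higher and 1 lower), 1 with group medians and 48 with single arrays as replicates. Over all 10 weeks limma called 0 of 2711 probes, with 110 at an unadjusted p under 0.05. Without single weeks each gene passed in 3 of 9 fits, both together without week 3 and without week 7, with adjusted p up to 0.0900 for Scd1 and 0.175 for Kif21a.

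Fatty acid oxidation genes in A/J had positive values in 13 of 19 cases (median 0.04), among them Hadh (0.39), Ehhadh (0.30), Bdh1 (0.23) and Acadvl (0.23), and the list missed the threshold with a camera adjusted p of 0.0549. Of the synthesis genes Scd1 alone passed, and Elovl5 stood at 0.46 and Fasn at -0.04. Camera in limma called 0 of 22 lists in A/J, and 4 of these had an unadjusted p under 0.05. Skeletal muscle markers were negative in 7 of 7 cases (median -0.12, adjusted p = 0.30), which held without centring, while 5 of 7 were negative after quantile normalization.

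Scd1 and Kif21a were higher on the high-fat diet in both strains, and limma on the weekly means called no gene for a difference between the strains. Scd1 was higher already at week 0, when too few arrays measured Kif21a for a test. In A/J Kif21a then stood at 0.41 (n = 2) in the high-fat and -0.43 (n = 1) in the low-fat group. In C57 it stood at -0.14 (n = 3) and -0.32 (n = 1). As C57 minus A/J, the diet difference of Scd1 differed by 0.05, that of Kif21a by 0.24, that of Nme4 by -0.57 and that of Crybb1 by -0.65. Limma called 0 of 7195 probes for a difference between strains, with 178 at an unadjusted p under 0.05, and 0 of 2711 with 70 over all 10 weeks, while with single arrays as replicates it called 3 of 7195. Camera called 0 of 22 lists for this difference, with 1, the hepatocyte genes, at an unadjusted p under 0.05. Across the 7195 probes, which are not independent replicates, the diet differences of C57 and A/J correlated with a Pearson r of 0.302 and a Spearman rho of 0.256. At an unadjusted p under 0.05 in both strains stood 69 probes, against 24.7 if the strains were unrelated, and 68 of them had the same sign.

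On the high-fat diet the mean of Scd1 was highest at week 6 in both strains. In C57 its log2 ratio on the high-fat diet went from 0.46 ± 0.68 (SD, n = 10) at week 1 to 2.33 ± 0.67 (n = 10) at week 5 and 2.73 ± 0.97 (n = 10) at week 6, and stood at 1.38 ± 0.94 (n = 10) at week 11. On the low-fat diet it ran from -0.36 ± 0.35 (n = 10) at week 1 to 0.79 ± 0.54 (n = 10) at week 7. In A/J the high-fat values were 1.51 ± 0.88 (n = 7) at week 5 and 1.63 ± 0.84 (n = 10) at week 6, against -0.74 ± 0.71 (n = 9) and -0.78 ± 0.93 (n = 6) on the low-fat diet, where week 7 stood at 0.21 ± 0.45 (n = 10) and week 9 at 0.37 ± 0.35 (n = 10). The weekly diet difference of Scd1 ran from 0.49 to 2.04 in C57 and from 0.46 to 2.41 in A/J.

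Scd1 was already higher in the high-fat groups at week 0. In C57 its log2 ratio was 0.32 ± 0.57 (SD, n = 9) in the high-fat and -0.27 ± 0.17 (n = 6) in the low-fat group, a difference of 0.58 (two-sided exact permutation p = 0.00999, adjusted 0.00999 over the 2 strains). In A/J it was 0.21 ± 0.44 (n = 8) against -0.94 ± 0.50 (n = 6), a difference of 1.14 (two-sided exact permutation p = 0.00133, adjusted 0.00266). These tests of a single gene were chosen after its values over the later weeks had been seen, and they take each array as independent, which the labels do not settle. With consecutive arrays averaged the difference was 0.69 in C57 (exact permutation p = 0.0476, n = 5 and 4) and 1.23 in A/J (exact permutation p = 0.00794, n = 5 and 5, the smallest it can give). In C57 7 of 9, and in A/J 7 of 8, high-fat arrays lay above all low-fat arrays. Among all probes of week 0 Scd1 did not pass in limma (adjusted p = 0.849 in C57 and 0.161 in A/J).

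**Figure D3:**
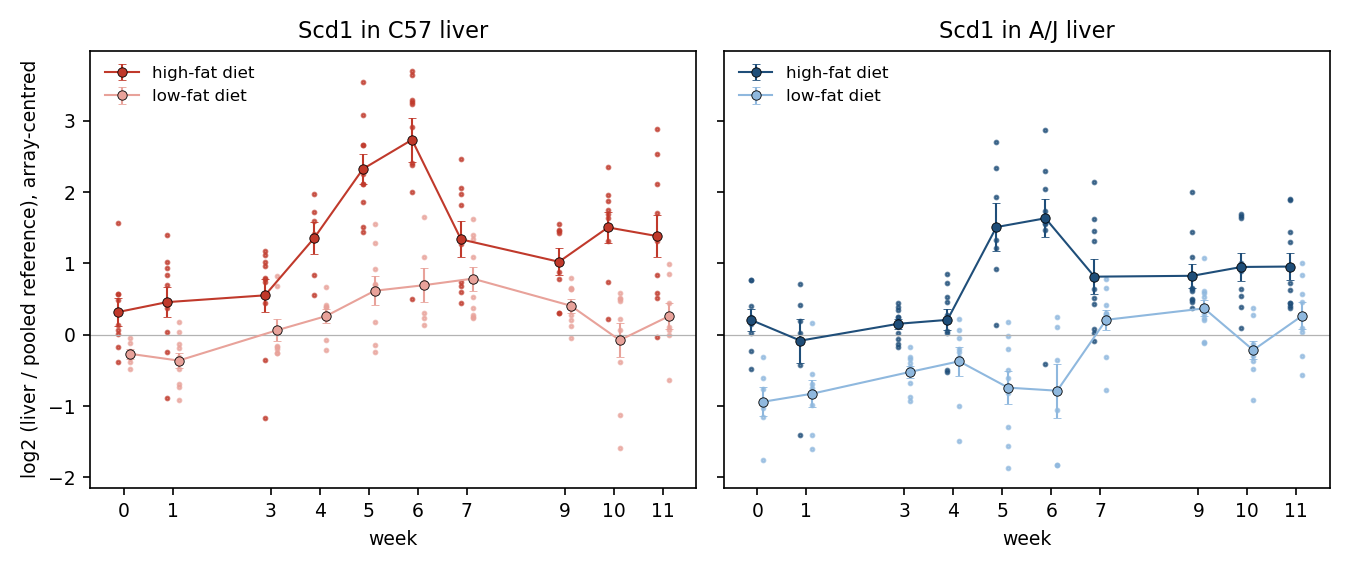
Log2 ratio of Scd1 in liver over the pooled reference (vertical axis) by week (horizontal axis) in C57 and A/J, with small points for arrays, circles for group means and bars for the SE over arrays, without week 8 and the 4 other arrays unlike the rest. The high-fat mean was 2.73 in C57 and 1.63 in A/J at week 6.

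Tests within single weeks called few genes except in A/J at week 4 and in C57 at week 8. Scd1 was called at week 5 in C57 (1.71, limma adjusted p = 0.0198, n = 10 and 9), and in A/J at week 5 (2.23, adjusted p = 0.0173, n = 8 and 9) and week 6 (2.40, adjusted p = 0.0315, n = 10 and 6). Letmd1 (-1.91) and Ubxn11 (1.65) were also called in A/J at week 6, both with an adjusted p of 0.0315, and 9130008F23Rik (-1.51, adjusted p = 0.0484, n = 5 and 3) in C57 at week 0. These 3 were named because the counts are small, after their values were seen. Averaging consecutive arrays, a block for the sample number and the looser filter each left 0 calls at week 5 in both strains. They also left 0 at week 6 in A/J. At week 5 in A/J limma called 0 probes without centring and after quantile normalization too. The stricter filter gave 0 in A/J at both weeks, but Scd1 was measured on too few arrays to be tested with it. The call at week 0 in C57 was lost without the unlike arrays (0 of 5816, with 331 at an unadjusted p under 0.05) and in 6 other settings. Limma called 0 probes in 8 of 10 weeks in C57 and in 7 of 10 in A/J, and the share at an unadjusted p under 0.05 ran from 2.85% to 36.7% and from 3.19% to 22.1%. Without week 8 and the unlike arrays it called 0 in 7 of 9 and 6 of 9 weeks, 2 probes in C57 at week 6 and 209 in A/J at week 4, and Scd1 in A/J at week 5 stood at 2.25 (limma adjusted p = 0.0481, n = 7 and 9). With the spread of all 44 groups pooled, limma called 719 probes in A/J at week 6 and 288 at week 8, against 3 and 0, and 91 at week 4 and 1524 at week 8 in C57. At week 0 in A/J it called 0 of 5675 probes, with 603 at an unadjusted p under 0.05.

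In A/J at week 4, 200 of 7336 probes passed the threshold, 54 higher and 146 lower on the high-fat diet. The largest rises were in 2810489J07Rik (1.08 ± 0.18, SE), Spg20 (1.01 ± 0.20) and Ewsr1 (0.99 ± 0.26), and the largest falls include those in the chromatin gene Daxx (-2.46 ± 0.51), 2810025M15Rik (-1.90 ± 0.36) and Knl1 (-1.81 ± 0.42), with limma adjusted p between 0.0102 for 2810489J07Rik and 0.0497 for Ewsr1. Of 49 genes of the respiratory chain and ATP synthase 5 fell and none rose, among them Atp5md (-1.04), Ndufb8 (-0.89) and Atp5pb (-0.88), and of 39 ribosomal protein genes 2 fell, Rps15 (-0.89) and Rplp1 (-0.83). The muscle gene Atp2a1 (-1.62) and Cyp2c55 (-1.52) were lower as well, and the matrix gene Col4a2 (0.55) was higher. After quantile normalization 0 of the respiratory chain genes were called, and 3 of the ribosomal protein genes were, all lower. No xenobiotic gene was called then, and 1 muscle and 1 matrix gene were higher. Without centring 7 respiratory chain, 3 ribosomal protein, 1 xenobiotic and 1 muscle gene were lower, and no matrix gene was called. The genes named for this week were chosen after the count was seen. The count moved between 65 and 424 when single arrays were left out, and fell to 16 with a block for the sample number and to 1 with consecutive arrays averaged. After quantile normalization 125 were higher and 100 lower, and without centring 7 and 189.

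In C57 at week 8, 653 of 3182 probes passed, 353 higher and 300 lower, and no gene is named from this comparison because 9 of its 10 high-fat arrays are among those unlike the rest. Without centring 211 probes were higher and 326 lower. The count was 227 with a block for the sample number and 418 with consecutive arrays averaged. With 1 high-fat array left, the week was not tested without the unlike arrays.

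Limma called no gene for a diet difference that changed in a straight line with week. Over 9 weeks 0 of 7195 probes passed in C57 (264 at an unadjusted p under 0.05) and 0 in A/J (298), and over 10 weeks 0 of 2711 in each (43 and 86). The low-fat groups showed no calls either, although unadjusted p-values under 0.05 were more frequent, 1153 of 7195 in C57 and 1062 in A/J (390 and 238 of 2711 over 10 weeks). The smallest limma adjusted p in the low-fat course was 0.0516 in C57 and 0.111 in A/J.

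Before the strains were compared, genes known to differ between them were examined. The complement gene Hc, which carries a loss-of-function change in A/J, was higher in C57, with a mean log2 ratio of -0.00 against -0.88 in A/J and a higher value in 17 of 18 combinations of diet and week. Nnt, which carries a deletion in some C57 substrains, stood at -1.07 in C57 and -1.01 in A/J and was higher in C57 in 9 of 18, and Dysf, disrupted by an insertion in A/J, at 0.54 and 0.62 (6 of 18). Nnt and Dysf thus showed no consistent strain difference. The part of each gene that its probe covers is not given, so whether either value should differ cannot be told.

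On the low-fat diet C57 liver had more RNA than A/J for Selenbp2, a selenium-binding protein gene, by a log2 difference of 1.14 ± 0.13, for the SUMO ligase gene Pias3 by 1.04 ± 0.16, for Secisbp2 by 1.03 ± 0.13, for Amigo1 by 1.02 ± 0.15, for the GABA receptor gene Gabra3 by 0.97 ± 0.17 and for Fshb by 0.97 ± 0.13. C57 had less for 4930565N06Rik (-1.56 ± 0.14), Lypd6b (-1.34 ± 0.12), the DNA repair helicase gene Ercc2 (-1.33 ± 0.17), Gfod2 (-1.13 ± 0.19), Sft2d3 (-1.08 ± 0.14) and the corepressor subunit gene Suds3 (-0.74 ± 0.10). Pias3 and Amigo1 kept their sign in 8 of 9 weeks and the other 10 in 9, with limma adjusted p from 2.13e-08 for Lypd6b and 4930565N06Rik to 0.000705 for Gabra3. An array cannot tell such a difference in RNA from a sequence difference under the probe. Secisbp2, and with it Nme4 (0.62) and Crybb1 (0.89), were higher in C57 here and lower on the high-fat diet in C57, but both comparisons share the C57 low-fat groups, so these are not independent. Secisbp2 stood at 1.32 in those groups, at 0.47 in C57 on the high-fat diet and at 0.28 and -0.01 in A/J on the low-fat and high-fat diets.

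In all, 183 of 7195 probes passed in limma, 115 higher and 68 lower in C57, without centring 186 passed, 151 higher and 35 lower, and after quantile normalization 278, 185 higher and 93 lower. Over all 10 weeks 35 of 2711 passed, 27 higher and 8 lower, and 32 of these were among the 183. The rule named from them Ckap5 (0.95 ± 0.15), Ptgdr2 (0.79 ± 0.18), 1700020N15Rik (0.76 ± 0.16), Notch2 (0.74 ± 0.15), Zfp474 (0.73 ± 0.14) and Capg (0.68 ± 0.15) as higher in C57. As lower it named Lypd6b (-1.37 ± 0.14), Melk (-0.83 ± 0.18), the carboxylesterase gene Ces1f (-0.72 ± 0.14), Suds3 (-0.70 ± 0.10), Prss22 (-0.66 ± 0.16) and Mrpl45 (-0.53 ± 0.13). The fit over all 10 weeks includes week 8, in which 10 of 10 A/J low-fat arrays were unlike the rest.

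Male-biased liver genes were higher in C57 on the low-fat diet, with 4 of 5 measured members positive and 2 past the threshold, the major urinary protein genes Mup3 (0.83) and Mup5 (0.90). The list passed in limma's camera (adjusted p = 0.00241) and also with an estimated correlation (adjusted p = 0.0175 with an estimated correlation), under every scaling tried and without each week in turn, but 13 of 100 groupings of the weekly means gave as many lists, so chance cannot be excluded. Over all 10 weeks only 1 member was measured, at -0.24. Mup genes are a family of near-identical copies that a probe can pick up together, so these 2 values may describe the family. Of the hepatocyte genes 1 of 16 passed, Trf, which was lower in C57 (-0.52). Adjusted over the list alone Alb was lower too (-0.34) and Ahsg was higher (0.38). Of 24 xenobiotic genes Cyp2c29 was higher (0.38), and adjusted over the list alone Gsta3 (0.50) and Gstm3 (0.28) were as well. The phosphofructokinase gene Pfkl (0.58, with a second probe at -0.10), Ndufb4 (0.45) of the respiratory chain and Rpl13a (0.40) of the ribosome also passed in C57. Among 12 histocompatibility genes H2-D1 (0.23) and H2-Q7 (0.23) passed only adjusted over the list alone.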

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

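Of the tests in this part, the 4 on week 8, the quantile tests and the pairings on week 4, the single-gene comparisons of Scd1 at week 0 and everything without week 8 were chosen only after the result was seen.

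Within groups of 4 to 10 arrays, a single array far from the others was found in 5 of 44 groups for the correlation with the median of all arrays, where chance gives about 2.2, and in 3 of 41 groups for Scd1, where chance gives about 2.05. For the correlation these were array 50 of A/J high-fat week 5 (0.149, group median 0.605), array 79 of A/J high-fat week 8 (0.606, median 0.0722), array 68 of C57 high-fat week 7 (0.365, median 0.531), array 72 of C57 high-fat week 8 (0.658, median 0.0719) and array 99 of C57 high-fat week 11 (0.518, median 0.697). For the log2 ratio of Scd1 they were array 60 of A/J high-fat week 6 (-0.40, median 1.61), array 3 of C57 high-fat week 0 (1.57, median 0.14) and array 60 of C57 high-fat week 6 (0.50, median 3.07).

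At week 8 in C57, 653 probes separated the diets, a number that none of the other 99 groupings of the arrays reached (1 of 100, highest other 166). Chance can thus be excluded as far as the arrays are independent. A response of the liver to the diet is argued against by the missing liver pattern of the high-fat arrays. Their median log2 ratio over 189 probes high in liver outside week 8 was 0.15 (interval over probes, not arrays, -0.04 to 0.26). In the low-fat arrays it was 0.95 (0.88 to 1.04). This largely restates the low correlation by which 9 of the 10 high-fat arrays were set apart, and is not a separate test. The hepatocyte genes (-0.10 in the 9 unlike arrays against 0.64) differed within their spread of 0.88. Noise from failed hybridisation is also argued against, because those arrays correlated with one another at a median of 0.490. A candidate explanation that stays open is that their values stand a few positions away from their probes: in 20 of 24 stretches of 720 probes the best correlation with the median of all arrays lay at a shift of 1 to 25 positions, as in 24 of 24 for both A/J groups, and in 0 of 24 for C57 low-fat. The gain was small. In C57 high-fat the median best correlation was 0.159 at such a shift and 0.104 at distant shifts, while C57 low-fat had 0.751 with no shift. The shifts in C57 high-fat differed between stretches, from -18 to 15, and 18 of the 20 were positive. In some stretches the best shift was the same in C57 high-fat and both A/J groups, as 7 in stretch 14. In others it differed, as in stretch 10, with -18 in C57 high-fat and 19 in each A/J group. No corrected values were made from these shifts.

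At week 4 in A/J, 200 probes separated the diets, against at most 2 in the other groupings (1 of 100). Chance can thus be excluded as far as the arrays are independent. The count was 1 with consecutive arrays averaged, as few as in 11 of 100 random pairings (median 54). It was 16 with a block for the sample number, but the numbers do not pair the arrays, so this count does not tell whether they are independent. A response shared with the other weeks of A/J is argued against by a correlation of -0.117 with their mean difference, which 96 of 100 groupings reached, though weeks 1, 3 and 6 of A/J did not resemble the others either (95, 53 and 84 of 100). A difference in scale is argued against as the whole cause, since 225 probes passed after quantile normalization, 135 of the 200 again, and all 200 kept their sign, but it stays open for the split of 54 higher and 146 lower, which turned to 125 and 100, and to 7 and 189 without centring. Whether single arrays account for it cannot be told apart: the count was between 65 (without high-fat array 40) and 122 with any 1 of high-fat arrays 35, 36, 37, 38 and 40 left out, and 92, 100, 110, 94 and 98 without low-fat arrays 32, 34, 36, 38 and 39, and it rose to 308 without high-fat array 32 and to 368 and 424 without low-fat arrays 30 and 31. A diet response of that week alone stays open as untested, and a batch of hybridisation cannot be examined because the labels give none.

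For the higher Scd1 in the high-fat groups at week 0, a general shift of the arrays was examined in A/J only. It is argued against there, since the log2 difference was 1.13 with each array centred and 1.44 after quantile normalization. In A/J the week 0 difference over all probes resembled the diet difference of the later weeks (r = 0.146, 1 of 100 groupings as high, highest other 0.138), which is consistent with groups that had already differed as by the diet. In C57 it did not (r = -0.00923, 53 of 100, highest other 0.203). Whether the animals had eaten the diets before week 0 is not given by the labels and stays open.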

How the results depend on the processing

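The fits without week 8 and without the arrays unlike the rest, with either probe filter, and the covariate for odd or even numbers were chosen only after the results were seen.

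Counts are of probes past the threshold, with the planned value first: 2 for diet in C57, 0 in A/J, 0 for their difference and 35 for strain. Without week 8 and the arrays unlike the rest they were 17, 2, 0 and 183 (15, 2, 0 and 176 with probes measured in 7 of 9 weeks), where more probes were tested. Leaving out each week gave 1 to 16 in C57, 0 to 2 in A/J and 24 to 175 for strain, each highest count without week 8; other weeks gave 1 to 3, 0 and 24 to 48. In C57 it was 1 without week 1, 4, 5, 6, 7, 9 or 11. Quantile normalization gave 8 in C57, 3 in A/J and 76 for strain, the looser filter 4 in C57 and 53 for strain, and the stricter filter, with fewer probes tested, 0 and 6. Without arrays standing apart from their group it was 4 in C57, group medians gave 1 in C57 and 1 in A/J, and C57 fitted alone gave 0. Except in the stricter filter, where fewer probes were tested, the cause was not tested.

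With single arrays as replicates the counts were 177, 35, 53 and 375, and with a block for the sample number 204, 22, 35 and 367; arrays of a group may share errors that these counts take as signal. The estimated block correlations were 0.0249, -0.0423, -0.0124 and 0.0125, and arrays of the same number and week resembled their own number most in only 10 of 94 cases in C57 and 9 of 87 in A/J, so the numbers do not pair the arrays.

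The low-fat course against week (0 in both strains) gave 7 in C57 after quantile normalization, 7 with the stricter filter, and in A/J 1 without centring and 0 to 1 when each week was left out (1 without week 6). The median weekly count (0 in both) was 0.5 in C57 with the stricter filter, and 11.5 in C57 and 35 in A/J when the spread of all 44 groups was pooled. At week 0 the single call in C57 went to 0 without centring, with quantile normalization, with the looser and the stricter filter, with consecutive arrays averaged, without the unlike arrays and with odd or even number as a covariate, and to 4 with pooled spread. In A/J it was 4 with the block for number and 2 with the odd or even covariate. The lists past the threshold went from 0 to 2 for diet in C57 and to 1 for strain without week 8. The cause of these shifts was not tested.

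The slopes of the diet difference were 0 in all 17 settings in both strains. Of the genes named over 9 weeks, 12 for strain stayed past the threshold in 186 of 186 values, 10 for diet in C57 in 124 of 156 and 2 for diet in A/J in 17 of 31, and none reversed. Over 9 weeks without centring the median of all probes was between -0.05 and 0.05. Signal over background, which limits the ratios, is not in the files.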

Other observations

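All tests in this part that leave out week 8, and the look at genes with several probes and at odd and even array numbers, were chosen only after the results were seen.

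Eif4a2, which encodes a helicase of translation initiation, was higher in C57 than in A/J on every probe tested. All 9 of its tested probes were higher in C57 on the low-fat diet, with log2 differences from 0.35 to 0.96, and 5 of them passed the threshold in limma. Of the 14 genes called for strain that had several tested probes, 7 had the same sign on all probes, and 0 had all probes past the threshold. Except in Eif4a2, only 1 probe of each gene passed, so calls in both directions could not occur in the others. Eif4a2 was chosen after its values were seen.

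The numbers of calls for diet in C57 and for strain are beyond what other groupings of the weekly group means gave. For diet in C57 1 of 100 groupings reached 2 probes over all weeks (highest other 1) and 1 of 100 reached 17 over 9 weeks (highest other 5). For strain the 35 and 183 probes were each reached by 1 of 100, with 5 and 23 as the highest others. Chance can be excluded for the number of calls for diet in C57 over 9 weeks and for strain. It is not excluded for each single call, since other groupings gave calls too. For diet in C57 over all weeks the count of 2 is close to the highest other, 1, so chance is not firmly excluded there. For diet in A/J over 9 weeks 2 of 100 gave 2 probes, the highest other being 2. That share is below the limit set beforehand, but another grouping gave as many calls, so chance is not firmly excluded there. For the correlation of both strains' diet differences, 0.302, 1 of 100 groupings was as high, and the highest other was 0.293, close to the real value.

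Chance cannot be excluded for the list tests. The 2 lists called for diet in C57 over 9 weeks were reached by 6 of 100 groupings (highest other 3), and the 1 list for strain by 13 of 100 (highest other 3).

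Where a result has 0 calls every grouping is as large (100 of 100), so the groupings say nothing about it. For these the highest others were 1 for diet in A/J and 0 for the difference between strains over all weeks, and 0 for that difference over 9 weeks. For lists they were 6 over all weeks, and 4 for A/J and 2 for the difference over 9 weeks. For the lines against week they were 1 for the diet difference and 4 for the low-fat course in C57 over all weeks, and 3 and 29 in A/J, and over 9 weeks 1, 3, 5 and 7 in that order. For the median weekly count the highest other was 0 in both strains, for week 0 in A/J it was 1, and the single call of week 0 in C57 was reached by 4 of 100 groupings, the highest other being 5.

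Arrays whose numbers were both odd or both even were more alike than others of their group in 34 of 43 groups, with a median correlation of 0.550 against 0.507. The labels give no meaning to the numbers.

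Identical columns were deposited for A/J high-fat arrays 13 and 14 of week 1 and for arrays 43 and 44 of week 5.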
